A study of Mus musculus with 3 samples.

How the data were processed

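CD4+ T cells were sorted from the kidneys and spleens of lupus-prone MRL/lpr mice with loxP-flanked Ezh2, with or without an inducible Cre (Cre fused to an estrogen receptor) under the Cd4 promoter. Per the labels, cells of 10 floxed and 9 Cre-carrying mice were sorted with antibodies to CD3, TCR beta, CD4 and CD8a. Tamoxifen was given at 300 mg/kg, starting at 10 weeks of age (preventative) or 14 weeks (therapeutic) and lasting to 24 weeks, and the labels do not say which mouse had which start. The floxed strain had been crossed to MRL/lpr for 6 generations. The GEO labels describe 3 samples, for the gene expression, antibody tag and T cell receptor libraries of the same cells, and receptor sequences were not analysed here.

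The deposited matrices, 1 per organ, hold whole UMI counts for 32285 gene rows and 10 antibody tag rows, with no normalization recorded by the authors. Per the file headers the counts came from Cell Ranger 7.1.0, and per the submitters' processing notes Cell Ranger 7.1.0, Seurat 5.0.1 and the mm10 (GRCm38) genome were used. Other settings of the alignment and of cell calling are not given in the sources used here. Each matrix joins 9 blocks of barcodes, told apart by a suffix, and the 18 blocks fall into 10 of the first day and 8 of the second day of the deposited tag key. The key gives a tag sequence for each mouse and organ and the matrices give tag numbers. They were joined by the order of the key and the tag maker's numbering, which give the same numbers. Genes are named by the symbols in the deposited matrices, and positions of 35 named genes, all 35 of which matched by symbol, were looked up in RefSeq genes of GRCm38.p6.

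Each of the 10 blocks of the first day was led by 1 tag in at least 99.5% of its cells, and the key gives that tag's mouse, organ and genotype. Cells were assigned by block, and 13 cells led by another tag were left out. HTODemux (Seurat 5.3.0, positive quantile 0.99), the rule planned for this step, kept 434 and 210 kidney cells of the KO mice and 3, 2 and 2 of the WT mice, so the block replaced it and its spleen singlets became an alternative. The 8 blocks of the second day held the same 2399 cells under 4 mice and both organs (17523 entries, 6 blocks with identical gene counts and smaller blocks of 2148 and 981 cells). Tag HTO1 led in at least 97.8% of cells in each of them, and the key gives HTO1 on that day to the kidney of 1 KO mouse (3414). In the largest kidney blocks its median was 530 UMIs against 281 for the next tag. Because the same cells also stood under the other mice and the spleen, they were given to no mouse and entered no comparison. The key lists 4 KO and 5 WT mice, of which 2 KO and 3 WT remained. Doublets were handled by tags alone and no doublet caller was run, so 2 cells of 1 mouse in a droplet could not be recognised. The cycling-like cluster, with a median of 11709 UMIs per cell, is where such droplets and large dividing cells would look alike.

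Of 13368 deposited cells of the first day (4989 kidney, 8379 spleen), 13337 had at least 200 genes and under 10% mitochondrial UMIs and were kept (4979 kidney, 8358 spleen). Median UMIs per cell lay between 3181 and 3521 in the kidney blocks and between 3209 and 3645 in the spleen blocks. Cells were scaled to 10000 counts and log-transformed. The Leiden method of igraph 0.11.9 clustered them (2000 variable genes, 30 principal components, a shared graph of 15 neighbours, resolution 1, seed 0). Scanpy 1.11.5 only held the counts. The 260 fixed list and marker genes were left out of the clustering. This gave 23 clusters. A cluster took the name of a fixed marker class, as "-like", where its markers had a mean log2 fold of at least 1, at least 3 were raised and at least 1 was among its 10 leading genes, and 8 clusters were named. The scoring rule was set after the counts were seen, while the markers were not. Clusters 11, 21 and 22, led by CD8, immunoglobulin and myeloid, and kidney tubule transcripts, were left out of the sums (323 cells), which left 13014 cells. Names rest on rebuilt clusters and may differ from those of the study.

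Counts were summed per mouse and organ (at least 30 cells each) and tested with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment at 0.05. The comparisons were KO against WT in kidney and in spleen, the difference of that effect between organs (interaction term), and kidney against spleen with genotype as a covariate. Levels are TMM-scaled CPM computed from the deposited counts. Fitted log2 fold changes used the default prior count of edgeR, and a prior count of 2 entered only the log2 CPM of the pairing check. Fixed gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation. Cell shares and Ezh2 levels were compared over mice by exact two-sided permutation, with shares adjusted by Benjamini-Hochberg over classes. Intervals at 95% (Wilson for shares, exact Poisson for counts) cover counting error alone.

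Kidney and spleen sums come from the same mice by the key, so the samples are paired. The check of that pairing, over 5963 genes, gave correlations of the deviations from group means between the organs of a mouse of 0.772, 0.775 and 0.539 for the WT mice and -0.014 for the KO mice, whose 2 values mirror each other. Fits with the mouse as a block were alternatives, in edgeR and in limma-voom with a consensus correlation of 0.393.

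Tests, lists, markers, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were Ezh2, then for each comparison the 10 largest rises and 10 largest falls past the threshold with a mean of at least 20 CPM in the higher group, up to 4 members of each list by smallest p, and the leading genes of clusters. Genes without a name of their own, receptor and immunoglobulin segments, mitochondrial, ribosomal and haemoglobin genes were passed over (1 called gene in spleen and 177 between organs). Values of other genes given per list or cluster were chosen after they were seen.

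The gene tests were tested on simulated data drawn from the real means and library sizes, with 200 genes changed. For kidney (10151 genes) edgeR recovered 19.2% of changes of 2-fold and 67.7% of 4-fold with 4 false calls, and DESeq2 1.42.0 recovered 30.3% and 69.7% with 14. For spleen (11529 genes) edgeR recovered 14% and 72.7% with 9 false calls, and DESeq2 42% and 87.9% with 41. For the interaction (11760 genes) edgeR recovered 0% and 43.4% and limma 0% and 30.3%, each with 0 false calls. For kidney against spleen (11760 genes) edgeR recovered 54% and 86% with 8 false calls, and DESeq2 59% and 89% with 28. No recovered gene had the wrong direction. Each simulated sum was drawn independently around 1 mean per gene, with neither a link between the organs of a mouse nor a split among mice of a genotype. The values hold for such sums and are not error rates of the real comparisons.

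Alternatives were DESeq2, DESeq2 size factors in edgeR, no filter on low counts, minimums of 10 and 100 cells, all cells kept, a mitochondrial limit of 5%, a minimum of 500 genes, a tag rule (the leading tag at least 3 times the next and at least 10 UMIs), the block, each mouse left out, Leiden resolutions of 0.5 and 1.5 and CPM by library total. Alternatives added after the data were seen were HTODemux singlets, edgeR with a term for each mouse, leaving out both WT2 and WT3, leaving out cluster 8, clustering with the fixed genes or without the called genes, Ezh2 without cycling-like or naive-like cells, leaving out mice for shares and Ezh2, and lists under every setting. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the rest.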

Results

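Lupus-prone MRL/lpr mice, a strain in which T cells accumulate and nephritis develops, were used to study CD4+ T cells in which Ezh2 was targeted for deletion. Ezh2 is the histone methyltransferase subunit of Polycomb repressive complex 2 (PRC2). The question, as the series title gives it, was how inducible loss of Ezh2 in these cells bears on the T cells that enter the kidney. Ezh2-floxed mice without Cre are called WT here, and floxed mice that also carried a tamoxifen-inducible Cre under the Cd4 promoter are called KO, as in the deposited tag key. Both genotypes received tamoxifen. CD4+ T cells sorted from kidney and spleen were marked with one antibody tag per mouse and organ (TotalSeq-C), pooled, and read by single-cell RNA sequencing of transcript 5′ ends. The tag key names 9 mice, and the cells of 5 of them, 2 KO and 3 WT, could be told apart in the deposited matrices. These mice are KO1, KO2, WT1, WT2 and WT3, each with cells from both organs.

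The per-mouse sums of CD4+ T cells held 680 kidney cells of KO1, 205 of KO2, 1528 of WT1, 1448 of WT2 and 935 of WT3. The spleen sums held 1313, 1563, 2285, 921 and 2136 cells of the same mice in that order. Total counts ran from 824732 UMIs (unique molecular identifiers, each standing for 1 captured transcript) in kidney KO2 to 6170495 in kidney WT1. In spleen they ran from 4097980 in WT2 to 9580051 in WT1. With 2 KO and 3 WT mice, the smallest p that an exact two-sided permutation test can give is 0.1, and with 5 paired mice it is 0.0625.

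Ezh2, the targeted gene, lies on chromosome 6 from 47530274 to 47595270 in GRCm38. Levels are given in CPM, counts scaled to a common library total by TMM. In kidney it stood at 69.8 ± 12.3 CPM (SD, n = 2) in KO mice and 133 ± 33.1 CPM (SD, n = 3) in WT mice. In spleen it stood at 52.6 ± 1.54 CPM (SD, n = 2) in KO mice and 129 ± 52.5 CPM (SD, n = 3) in WT mice. Every KO mouse lay below every WT mouse in both organs, and WT1 was the WT mouse nearest to them, with 95.5 CPM in kidney and 69.6 CPM in spleen. The mean log2 difference was -0.91 in kidney (exact two-sided permutation p = 0.2) and -1.20 in spleen (exact p = 0.2). The edgeR quasi-likelihood fit gave log2 fold changes of -0.87 ± 0.25 (SE, adjusted p = 0.363) in kidney and -1.29 ± 0.38 (SE, adjusted p = 0.194) in spleen. Without naive-like and cycling-like cells the spleen level by library total was 67.2 and 61.6 CPM in KO1 and KO2 and 71.2, 133 and 130 CPM in WT1, WT2 and WT3. Counts from the 5′ end cover the start of the transcript, and the labels do not say which exons are floxed, so the level is a limited check of the deletion.

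**Figure D1:**
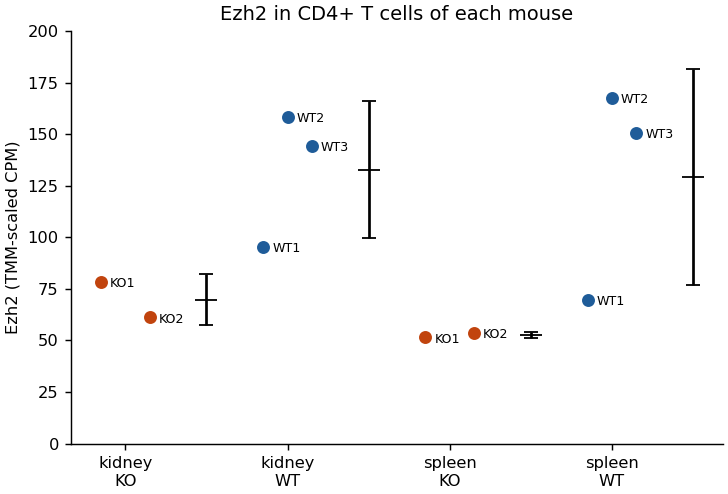
Ezh2 in CD4+ T cells of each mouse, in TMM-scaled CPM on a linear axis from 0; points are mice and the black bars beside them are the group mean ± SD (n = 2 KO, n = 3 WT). KO mice lie between 51.5 and 78.5 CPM and WT mice between 69.6 and 168 CPM over both organs, and within each organ every KO mouse lies below every WT mouse.

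The genotype comparison asked first whether the makeup of the CD4+ T cells differed. Naive-like cells, clusters with high Ccr7, Lef1 and other genes of resting recirculating T cells, made up 44.1% ± 10.8 (SD, n = 2) of spleen cells in KO mice and 1.63% ± 0.701 (SD, n = 3) in WT mice. In kidney they made up 15.4% ± 4.66 (SD, n = 2) in KO mice and 0.453% ± 0.465 (SD, n = 3) in WT mice. Cytotoxic-like cells, with granzyme B and the chemokines Ccl3 and Ccl4 among their leading genes, made up 2.80% ± 2.04 (SD, n = 2) of spleen cells in KO mice and 42.7% ± 28.3 (SD, n = 3) in WT mice. The WT mice were unequal here, with 11.3% in WT1 (95% Wilson interval 10.1 to 12.6), 66.1% in WT2 (62.9 to 69.0) and 50.9% in WT3 (48.8 to 53.0). Ifng and Havcr2, an inhibitory receptor gene, were also among the leading genes of the cytotoxic-like cells. Regulatory T-like cells, marked by Foxp3, made up 18.0% ± 6.96 (SD, n = 2) of spleen cells in KO mice and 6.48% ± 8.75 (SD, n = 3) in WT mice, where WT1 alone reached 16.5% (95% Wilson interval 15.0 to 18.0).

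Both naive-like differences lay at the smallest p the design allows, with all KO mice above all WT mice (exact two-sided permutation p = 0.1 in each organ). Benjamini-Hochberg adjustment over the 5 classes of an organ gave 0.375 in spleen and 0.5 in kidney for these exact tests, so no class passed a threshold of 0.05. The spleen exact p-values of the other classes were 0.2 for cytotoxic-like, 0.3 for regulatory T-like, 0.3 for cycling-like (0.922% against 3.06%) and 1 for follicular helper-like cells (8.40% against 8.002%). The last WT mean joined 23.3% in WT1 with 0% in WT2 and 0.746% in WT3, and the difference went from 0.395 points to 8.02 without WT1 and -3.61 without WT2. In kidney the exact p-values were 0.3 for cytotoxic-like cells (0.685% in KO against 3.88% in WT mice) and 0.2 for regulatory T-like cells (3.34% against 0.7105%). The kidney cytotoxic-like shares overlapped between genotypes, with 0% in KO1, 1.37% in KO2, 0.614% in WT1, 4.91% in WT2 and 6.12% in WT3. Kidney follicular helper-like cells (6.01% against 3.18%, exact p = 0.6) and cycling-like cells (1.01% against 1.57%, exact p = 0.9) overlapped too. Clusters made also without the 33 genes called between genotypes gave naive-like differences, KO minus WT, of 42.3 percentage points in spleen and 14.7 in kidney. The kidney cytotoxic-like difference was -3.25 points in those clusters and -20.4 points in clusters made without the 2654 genes called between genotypes or organs, and the kidney regulatory T-like difference was 7.05 and 6.95 points in them, in place of 2.63 points, and 1.23 points at a Leiden resolution of 1.5. Without those 2654 genes the spleen cytotoxic-like difference was -26.3 points, in place of -39.9. The highest KO share there was 1.39% and the lowest WT share 2.01%. In spleen nearly all naive-like cells came from cluster 2, and in kidney most came from cluster 16. Clusters 20, 10 and 13, which had raised naive, regulatory T and cycling markers but none among their 10 leading genes, were left unnamed. Their spleen means were 1.40% in KO against 0.0435% in WT mice for cluster 20, 5.01% against 2.06% for cluster 10 and 0.638% against 2.69% for cluster 13, and in kidney each stood under 1% in both genotypes. WT1 carried the WT means of the last 2, with 5.87% of its spleen cells in cluster 10 and 6.79% in cluster 13, against 0% and 0.326% (cluster 10) and 0.542% and 0.746% (cluster 13) in WT2 and WT3.

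**Figure D2:**
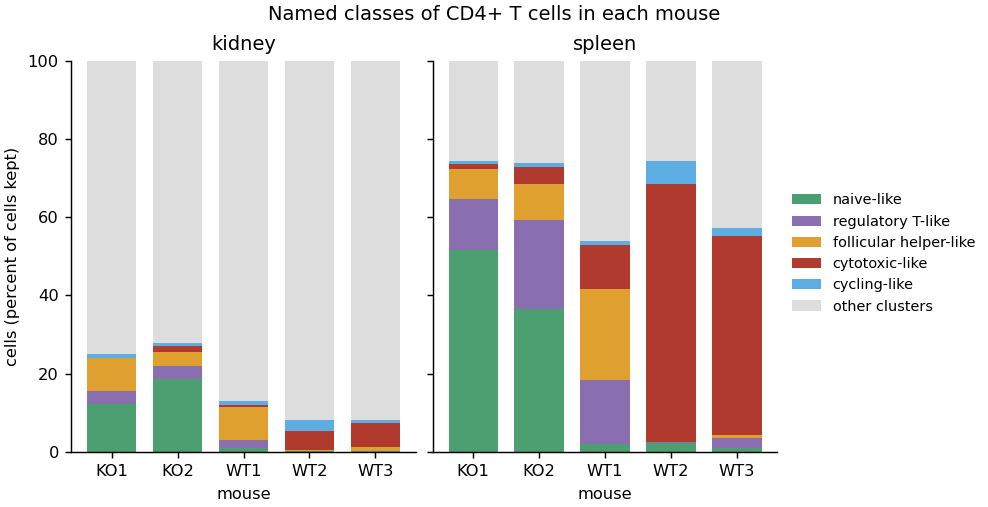
Share of each named class among the cells kept, as stacked bars in percent from 0 to 100 for each mouse, kidney at left and spleen at right; grey is all other clusters. Naive-like cells reach 36.5% and 51.7% of spleen cells in KO2 and KO1 and at most 2.17% in the WT mice, while cytotoxic-like cells reach 66.1% in WT2 and 50.9% in WT3.

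In spleen CD4+ T cells, Igfbp4 and Lef1 were among the genes that rose in KO mice and Eomes among those that fell. Igfbp4, an insulin-like growth factor binding protein, stood at 1121 ± 465 CPM (SD, n = 2) in KO mice and 30.02 ± 14.1 CPM (SD, n = 3) in WT mice, a log2 fold change of 5.21 ± 0.47 (SE). Lef1, a transcription factor of naive T cells, stood at 567 ± 58.7 against 112 ± 24.1 CPM, a log2 fold change of 2.34. Eomes, a transcription factor of cytotoxic T cells, fell from 311 ± 72.9 CPM (SD, n = 3) in WT mice to 55.1 ± 13.5 CPM (SD, n = 2) in KO mice, a log2 fold change of -2.49 ± 0.28 (SE). Anxa2, which encodes annexin A2, fell with it, from 334 ± 51.9 to 115 ± 10.2 CPM. Bcl2l11, which encodes the pro-apoptotic protein Bim, rose from 13.1 ± 2.07 to 40.7 ± 6.63 CPM.

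The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 33 of 11634 spleen genes, 28 higher and 5 lower in KO mice. The 10 largest rises were those of Igfbp4 (adjusted p = 0.0299), Amigo2 (log2 fold change 4.52), Pdlim4 (4.51), Plaur (4.40), Ly6c1 (4.0004), Myo10 (3.54), Tdrp (3.30), Bambi (3.08), Gpr146 (2.78) and Maff (2.57), by edgeR. The 5 falls were those of Eomes (adjusted p = 0.0448 by edgeR), Tmem163 (-2.22), Car5b (-2.21), Scd2 (-1.64) and Anxa2 (-1.53). Plaur encodes the urokinase receptor, Bambi a decoy receptor of the TGF-beta family, and Scd2 a fatty acid desaturase. Amigo2, Igfbp4, Lef1, Ly6c1 and Pdlim4 are 5 genes that also lead the naive-like cluster 2. Plaur, Gpr146, Maff and Igfbp4 are among the 10 leading genes of cluster 16, the other naive-like cluster. The summed counts and the cell shares are thus not independent of each other. Leaving out KO1, KO2, WT2 or WT3 left 0 called genes by edgeR (774, 1032, 1431 and 1395 at an unadjusted p under 0.05), and leaving out WT1 gave 2294. DESeq2 called 660 genes (363 higher, 297 lower), with all 33 among them. Without both WT2 and WT3 the WT arm holds WT1 alone, so its spread cannot be seen and that fit adds no support. Without KO1 or KO2 the KO arm likewise holds only the other KO mouse. Without the cells of cluster 8, whose Cd8a and Cd8b1 were raised, 32 of the 33 stayed called and Bcl2l11 did not.

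Grouped by the fixed lists, the circulation and naive genes stood highest in KO spleen, with a median log2 fold change of 2.06 over 12 tested members. Lef1 and Igfbp4 rose and 10 did not pass over all genes tested, while 9 of the 12 rose when adjusted over the list alone. Among the others, Actn1 stood at 163 against 20.6 CPM and S1pr1, the receptor by which T cells leave lymphoid tissue, at 146 against 41.2 CPM. The camera set test put the list up (adjusted p = 1.6e-26; adjusted p = 0.0911 with an estimated correlation). Cytotoxic effectors were down as a list, with a median of -1.95 over 10 members (camera adjusted p = 4.99e-10; adjusted p = 0.152 with an estimated correlation). None of the 10 passed over all genes tested, and 6 fell when adjusted over the list alone. Perforin (Prf1) stood at 21.0 ± 2.59 CPM (SD, n = 2) in KO and 89.8 ± 30.9 CPM (SD, n = 3) in WT mice, and Nkg7 at 352 against 1779 CPM. WT2 and WT3 stood apart, with Nkg7 at 2231 and 2229 CPM in them against 875 in WT1, and Gzmb at 300 and 105 against 46.7 CPM.

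The Th17 list was up in KO spleen with a median of 1.89 over 8 members (camera adjusted p = 1.7e-08; adjusted p = 0.0911 with an estimated correlation), and 5 rose when adjusted over the list alone. Its members were low: Il17a stood at 3.24 against 0.0307 CPM and the receptor Il23r at 5.27 against 0.244 CPM, while Ramp1 stood at 81.9 against 12.7 CPM. Cell cycle genes were down with a median of -1.06 over 16 members (camera adjusted p = 4.99e-10; adjusted p = 0.357 with an estimated correlation), and 8 fell when adjusted over the list alone. Top2a stood at 48.8 against 112 CPM and Mki67 at 46.7 against 117 CPM. WT2 stood apart in dividing cells. Cycling-like cells made up 5.97% of its spleen cells, against 1.13% and 2.10% in WT1 and WT3 and 0.831% and 1.01% in KO1 and KO2. B cell transcripts, a list for free RNA or other cells, were up with a median of 1.34 over 7 members (camera adjusted p = 0.00485; adjusted p = 0.357 with an estimated correlation), 2 of them when adjusted over the list alone, with H2-Aa at 37.7 against 7.59 CPM, while the immunoglobulin gene Igkc stood at 145 against 244 CPM. Ezh2 and Mtf2 had the smallest p among 10 PRC2 subunits, whose median was -0.25 with no call (camera adjusted p = 0.0731), 0 of them when adjusted over the list alone. Of 12 genes reported under PRC2 control in T cells, Bcl2l11 rose and Eomes fell, 2 rose and 6 fell when adjusted over the list alone, and the list did not pass (median -0.56, camera adjusted p = 0.0731).

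Other spleen lists did not pass camera. Chemokine receptors and adhesion genes had a median of -0.21 (camera adjusted p = 0.189), with 3 rising and 5 falling when adjusted over the list alone; Cxcr5, which guides T cells to B cell follicles, stood at 24.7 against 79.7 CPM. Effector cytokines and chemokines had a median of -0.26 (0.0731), with 2 rising and 5 falling when adjusted over the list alone, among them Ccl3 at 29.5 against 462 CPM (150 in WT1). Camera adjusted p-values were 0.0731 for tissue residency (median -0.43, 1 up and 3 down when adjusted over the list alone) and 0.339 for inhibitory receptors (-0.15, 1 up and 4 down). For regulatory T genes the value was 0.21 (median 0.37, 0 when adjusted over the list alone), and for follicular helper genes it was 0.0731 (-0.24, 3 down). Glycolysis gave 0.0655 (-0.21, 2 down when adjusted over the list alone) and survival and death genes 0.61 (-0.05, 1 up and 2 down). Stress and immediate early genes gave 0.21 (median 0.09, 2 up and 1 down when adjusted over the list alone). The type I interferon list had a median of -0.06 but a mean of 0.09 and a camera direction up (0.488), and Usp18 alone rose, also when adjusted over the list alone. Among transcripts of other cells, CD8, gamma-delta and NK genes gave 0.142 (median 0.85, 2 up when adjusted over the list alone), with Cd8b1 at 26.2 against 7.74 CPM and Klrd1 at 6.23 against 12.3 CPM, and kidney tubule genes 0.488 (median 0.53). Myeloid transcripts had 1 tested member (Cst3, log2 fold change -0.16), and erythroid and platelet transcripts had none that could be tested in any comparison.

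**Figure D3:**
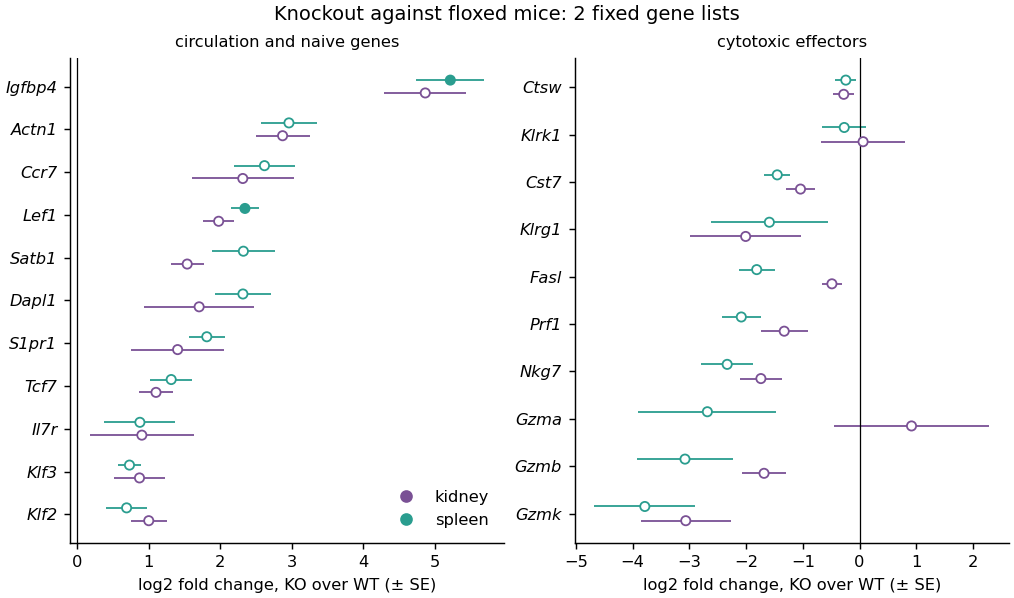
Log2 fold change, KO over WT, of the tested members of the circulation and naive list (left, 1 member not drawn) and of the cytotoxic effector list (right), with SE bars, in kidney (purple) and spleen (green); filled points passed the edgeR test at an adjusted p under 0.05. The medians over all tested members are 1.62 in kidney and 2.06 in spleen at left, and -1.18 in kidney and -1.95 in spleen at right, and Lef1 and Igfbp4 in spleen are the filled points.

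In kidney CD4+ T cells no gene passed the test between genotypes, and the values of the same kinds of genes lay apart. Igfbp4 stood at 286 ± 4.25 CPM (SD, n = 2) in KO and 9.67 ± 8.75 CPM (SD, n = 3) in WT mice, and Lef1 at 342 ± 95.3 against 88.2 ± 13.9 CPM. Gzmk, which encodes granzyme K, stood at 103 ± 22.4 CPM (SD, n = 2) in KO and 866 ± 586 CPM (SD, n = 3) in WT mice, of which WT1 held 192 CPM and WT2 and WT3 1261 and 1145 CPM. Ccr2, a receptor for inflammatory chemokines, stood at 25.0 ± 6.92 against 267 ± 175 CPM, again with WT1 (64.3 CPM) far below WT2 and WT3 (376 and 359 CPM). Cxcr6, a receptor of tissue T cells, stood at 72.4 ± 9.90 against 143 ± 7.65 CPM, and Bcl2l11 at 74.2 ± 3.70 against 40.6 ± 3.77 CPM.

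The edgeR quasi-likelihood test called 0 of 10302 kidney genes at an adjusted p under 0.05, with 1124 genes at an unadjusted p under 0.05, and DESeq2 called 90 (61 higher, 29 lower). The smallest adjusted p among the named genes was that of Cd8b1 (0.125 by edgeR), with 59.0 ± 4.33 CPM (SD, n = 2) in KO and 13.5 ± 2.93 CPM (SD, n = 3) in WT mice. Leaving out WT1 gave 1249 genes, no filter on low counts gave 545, and leaving out both WT2 and WT3 gave 172.

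Of 19 kidney lists tested, camera put 5 up and 2 down. The circulation and naive genes were up with a median of 1.62 over 12 members (adjusted p = 1.02e-26; adjusted p = 0.144 with an estimated correlation), and 7 rose when adjusted over the list alone. Cytotoxic effectors were down with a median of -1.18 over 10 members (adjusted p = 2.33e-07; adjusted p = 0.144 with an estimated correlation), and 5 fell when adjusted over the list alone. WT2 and WT3 stood apart here, with Nkg7 at 2384 and 2274 CPM in them, 1025 in WT1 and 629 and 476 in KO1 and KO2. The Th17 list was up with a median of 2.05 over 7 members (adjusted p = 1.56e-08; adjusted p = 0.144 with an estimated correlation), 3 of them when adjusted over the list alone, and Ccr6 stood at 10.3 against 1.08 CPM. Transcripts of CD8, gamma-delta and NK cells were up with a median of 1.92 over 3 members (adjusted p = 1.56e-08; adjusted p = 0.144 with an estimated correlation), where Cd8a and Cd8b1 rose when adjusted over the list alone and the third member, Klrd1, stood at 20.9 against 32.3 CPM. B cell transcripts were up with a median of 1.68 over 5 members (adjusted p = 0.000421; adjusted p = 0.144 with an estimated correlation), 3 of them when adjusted over the list alone, and H2-Aa stood at 32.0 against 5.66 CPM, while the immunoglobulin gene Igkc stood at 120 against 241 CPM. Stress and immediate early genes were up with a median of 0.28 over 16 members (adjusted p = 0.00114; adjusted p = 0.587 with an estimated correlation), 2 of them when adjusted over the list alone, and Fos stood at 1028 against 640 CPM. The type I interferon list was down with a median of -0.38 over 15 members (adjusted p = 0.0161; adjusted p = 0.587 with an estimated correlation), 0 of them when adjusted over the list alone, and Irf7 stood at 113 against 225 CPM (132 in WT1).

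No member of any kidney list passed over all genes tested. Among lists that did not pass camera in kidney, effector cytokines and chemokines had a median of -0.29 (adjusted p = 0.0937, 3 down when adjusted over the list alone), with Ccl5 at 2607 against 10238 CPM (5178 in WT1). Genes reported under PRC2 control had a median of -0.37 with a mean of 0.01 and a camera direction down (adjusted p = 0.432), and 2 rose and 4 fell when adjusted over the list alone. The PRC2 subunits (median -0.01, 0.496, 0 when adjusted over the list alone), cell cycle genes (-0.16, 0.523, 0) and glycolysis genes (-0.05, 0.308, 0) did not pass. Regulatory T genes (0.67, 0.0937, 0) did not pass, with Foxp3 at 50.5 against 14.3 CPM (36.0 in WT1). Inhibitory receptors (median 0.17, 0.674, 0) and follicular helper genes (0.15, 0.484, 1 down) had a positive median and a camera direction down, and the mean of the follicular helper list was -0.15. Tissue residency genes (-0.04, 0.322) had 1 member down when adjusted over the list alone, Cxcr6. Chemokine receptors and adhesion genes (-0.17, 0.308) had 1 up and 2 down, and survival and death genes (0.17, 0.693) had 2 up and 1 down. Myeloid transcripts gave a median of -0.75 over 2 members (0.308), and the kidney tubule list had 1 tested member, Napsa, with a log2 fold change of -0.89.

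Whether the genotype difference itself differed between organs was tested with an interaction term. Fasl, the ligand of the death receptor Fas, stood at 243 against 348 CPM (KO against WT) in kidney and at 52.5 against 185 CPM in spleen. Ifng, which encodes interferon gamma, stood at 197 against 322 CPM in kidney and at 112 against 556 CPM (204 in WT1) in spleen. Bcl2l11 differed by 0.89 on the log2 scale in kidney and 1.62 in spleen, and Cd160 stood at 1.47 against 1.80 CPM in kidney and 14.5 against 4.64 CPM in spleen.

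None of these passed: edgeR called 0 of 11842 genes for the interaction, with 362 at an unadjusted p under 0.05. DESeq2 called 1, edgeR with a term for each mouse called 2, limma-voom with the mouse as a random block called 0, and leaving out both WT2 and WT3 gave 18 by edgeR. Camera put 2 lists up and 1 down for kidney minus spleen, and each call was lost with an estimated correlation (adjusted p = 0.356 for all 3). Cell cycle genes had a median of 0.80 over 16 members (adjusted p = 1.38e-10, 0 when adjusted over the list alone), with the KO mice lower than the WT mice by less in kidney than in spleen. Cytotoxic effectors had a median of 0.63 over 10 members (adjusted p = 0.000669, 0 when adjusted over the list alone), and the type I interferon list a median of -0.45 over 16 members (adjusted p = 0.000669, 1 down when adjusted over the list alone). The naive list gave a median of -0.29 over 12 members and did not pass (adjusted p = 0.551). Effector cytokines (0.60, adjusted p = 0.0538) and PRC2 subunits (0.19, adjusted p = 0.0783) did not pass either, nor did the others, whose medians ran from -1.42 for kidney tubule transcripts to 0.32 for genes reported under PRC2 control. In the follicular helper list the median was 0.21 and the mean -0.29, with a camera direction up, and in the survival and death list the median was -0.02 and the mean 0.04.

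Kidney and spleen CD4+ T cells of the same 5 mice differed in many genes. Crem and Fosl2, transcription factors of activated and tissue T cells, rose to 247 ± 91.0 CPM and 217 ± 85.2 CPM (SD, n = 5) in kidney from 27.9 ± 6.80 CPM and 28.5 ± 10.2 CPM (SD, n = 5) in spleen. Cdh1, which encodes E-cadherin, rose from 1.31 ± 1.17 to 23.3 ± 9.24 CPM, and Ramp3, a receptor activity-modifying protein, from 14.7 ± 10.9 to 190 ± 87.3 CPM. Art2b, an ADP-ribosyltransferase of T cells, fell from 36.6 ± 21.1 CPM in spleen to 4.91 ± 3.46 CPM in kidney, and Egr2 from 26.6 ± 10.7 to 8.31 ± 2.78 CPM. Of the AP-1 genes, Fos fell from 1997 ± 712 to 795 ± 246 CPM and Jun from 1617 ± 786 to 534 ± 229 CPM. Ezh2 stood at 108 ± 42.1 CPM in kidney and 98.7 ± 56.1 CPM in spleen and did not pass (adjusted p = 0.612 by edgeR).

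The edgeR quasi-likelihood test, with genotype as a covariate, called 2635 of 11842 genes, 1506 higher and 1129 lower in kidney. The 10 largest rises were those of Cdh1 (log2 fold change 3.99 ± 0.53, SE, adjusted p = 0.000557), Ramp3 (3.88), Ppp2r2c (3.55), Grb7 (3.18), Crem (3.15), Fosl2 (2.95), Dgat1 (2.86), Osgin1 (2.85), Abcb1b (2.77) and Vps37b (2.70). The 10 largest falls were those of Phactr1 (-3.93 ± 1.09, SE, adjusted p = 0.0270), Art2b (-2.59), Ephx1 (-1.82), Igfbp4 (-1.77), Egr2 (-1.70), Jun (-1.61), Fos (-1.36), Trim21 (-1.27), Apex1 (-1.20) and Tor4a (-1.19). Phactr1 stood at 307 CPM in spleen of WT1 and between 8.55 and 29.7 CPM in the other 4 spleens, and Ppp2r2c (20.6 ± 21.9 CPM in kidney) and Osgin1 (23.3 ± 18.8 CPM) had an SD near their mean. Cluster 8, which has Cdh1, Klrk1 and Klrd1 among its leading genes and Cd8a and Cd8b1 raised, stayed in the sums, with 4.22% to 15.5% of kidney and at most 0.503% of spleen cells per mouse. Without it 2305 genes were called by edgeR and Cdh1 still rose, as did Klrk1 and Cd8a, while Cd8b1 and Klrd1 no longer passed, nor did Lef1, S1pr1, Selplg and Ifi203. With the mouse as a block the count was 4082 (2139 higher, 1943 lower), and without KO1, KO2 or WT3 it was 1385, 1499 or 1575. Kidneys were dissociated with enzymes under heating and spleens were mashed, per the labels, so organ and dissociation cannot be told apart.

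Tissue residency genes rose in kidney as a list, with a median log2 fold change of 1.16 over 11 members (camera adjusted p = 5.84e-06), and the call held with an estimated correlation (adjusted p = 0.0206). With an estimated correlation it did not pass with the mouse as a block (camera adjusted p = 0.170) or without KO1 (0.0741), KO2 (0.0653) or WT1 (0.114). Crem, Rgs2, Cxcr6, Itga1, Bhlhe40 and Rgs1 rose, also when adjusted over the list alone (6 up and 1 down). Cxcr6 stood at 115 ± 39.5 against 23.5 ± 12.4 CPM (SD, n = 5), and Itga1, the integrin chain of a collagen receptor, at 11.1 ± 4.97 against 1.34 ± 0.886 CPM. Cd69, a marker both of residency and of recent activation, fell. Of 12 circulation and naive genes, Klf3 and S1pr1 rose and Igfbp4 and Lef1 fell (2 up and 3 down when adjusted over the list alone), and the list did not pass (median -0.17, camera adjusted p = 0.761). Stress and immediate early genes went both ways: Nr4a1, Jund, Fosb and Atf3 rose and Fos, Dusp1 and Jun fell (5 up and 4 down when adjusted over the list alone). Their median was -0.26, their mean -0.12 and the camera direction up (adjusted p = 0.966).

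**Figure D4:**
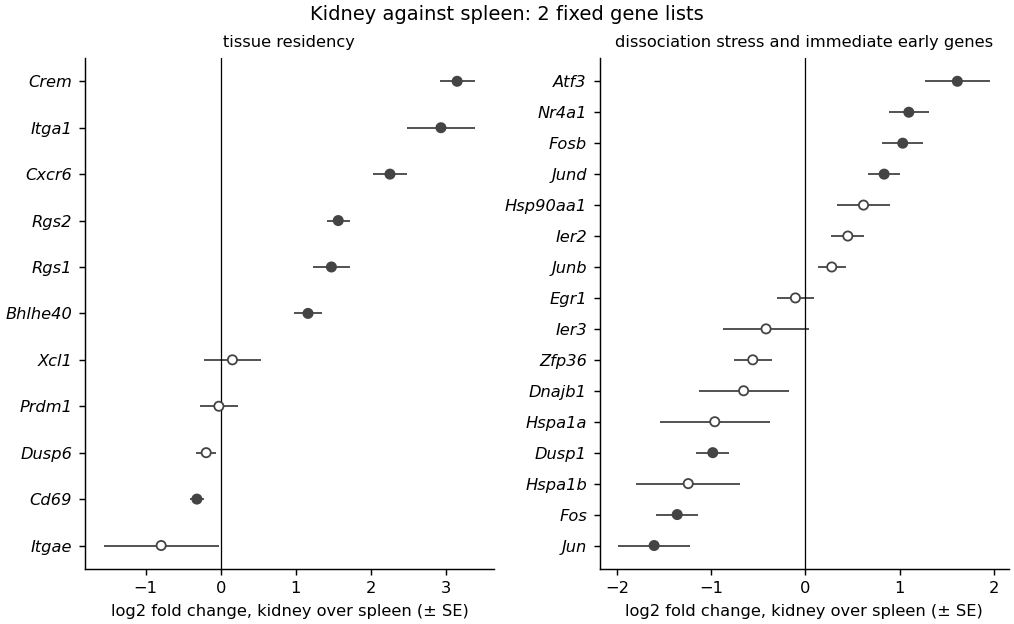
Log2 fold change, kidney over spleen, of each tested member of the tissue residency list (left) and the stress and immediate early list (right), with SE bars; filled points passed the edgeR test at an adjusted p under 0.05. Among residency genes 6 lie filled above 0 and Cd69 filled below it, and among stress genes 4 lie filled above 0 and 3 below it.

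Of 17 chemokine receptor and adhesion genes, Cxcr4, Cd44 and Selplg rose in kidney (3 up when adjusted over the list alone, median 0.40, camera adjusted p = 0.176). Tgfb1, Il2, Il17a and Tnfsf11 rose among effector cytokines, whose median was -0.18 with a mean of 0.21 and a camera direction up (5 up when adjusted over the list alone, adjusted p = 0.557). Il2 stood at 11.7 ± 5.30 against 2.18 ± 1.76 CPM (SD, n = 5), and Tnfsf11, which encodes RANKL, at 153 ± 95.3 against 38.7 ± 23.0 CPM. Ctsw, Fasl and Klrk1 rose and Cst7 fell among cytotoxic effectors (4 up and 1 down when adjusted over the list alone, median 0.43, adjusted p = 0.176). Bcl2l11, Cdkn1a and Tbx21 rose among genes reported under PRC2 control (3 up when adjusted over the list alone, median 0.32, adjusted p = 0.176), and Aebp2 rose among PRC2 subunits (1 up, median 0.21, adjusted p = 0.581). Bcl2l11, Fasl, Bcl2l1 and Pmaip1 rose among survival and death genes (4 up when adjusted over the list alone, median 0.23, adjusted p = 0.176). Slc2a1, the glucose transporter, rose with Gapdh, Hk2, Ldha and Hif1a while Pfkl fell (6 up and 1 down when adjusted over the list alone, median 0.11, adjusted p = 0.391).

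Rora and Il17a rose among Th17 genes (2 up when adjusted over the list alone, median 0.68, camera adjusted p = 0.543), and Icos rose among follicular helper genes (1 up, median -0.27, adjusted p = 0.761). Irf7 and Isg15 rose and Ifi203 and Usp18 fell among interferon genes (2 up and 2 down when adjusted over the list alone, median 0.19, adjusted p = 0.675). Cd160 fell among inhibitory receptors (1 down when adjusted over the list alone, median -0.06, adjusted p = 0.557), and Pcna rose among cell cycle genes (1 up, median -0.17, adjusted p = 0.781). No regulatory T gene passed (0 when adjusted over the list alone, median -0.44, adjusted p = 0.557). Among transcripts of other cells, Cd8a, Cd8b1 and Klrd1 rose (3 up when adjusted over the list alone, median 1.23, adjusted p = 0.176). B cell transcripts (median -0.97, adjusted p = 0.274), myeloid transcripts (0.35, adjusted p = 0.761) and kidney tubule transcripts (-0.36, adjusted p = 0.761) did not pass, with 0 called in each when adjusted over the list alone.

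The shares of the cell classes were also compared between the organs of a mouse, and no class passed. Cytotoxic-like cells made up 2.60% ± 2.74 of kidney and 26.8% ± 29.7 of spleen cells (SD, n = 5), naive-like cells 6.44% ± 8.53 against 18.6% ± 23.9, and regulatory T-like cells 1.76% ± 1.65 against 11.1% ± 9.49. Each of these 3 classes was lower in kidney in 5 of 5 mice, which gives the smallest p possible (exact paired permutation p = 0.0625, Benjamini-Hochberg 0.104). The naive-like difference, kidney minus spleen, was -39.6 and -17.7 percentage points in KO1 and KO2 and -0.904, -1.90 and -0.733 points in WT1, WT2 and WT3, and its mean went from -12.2 to -5.32 points without KO1. The cytotoxic-like difference was -61.1 and -44.8 points in WT2 and WT3 and between -10.7 and -1.36 points in the other mice. The regulatory T-like difference was -9.58, -19.7, -14.4, -0.217 and -2.64 points in KO1, KO2, WT1, WT2 and WT3. In WT2 it rested on 0 of 1467 kidney cells and 2 of 922 spleen cells, so its direction there is not secure. Clusters made without the 2654 genes called between genotypes or organs kept naive-like cells (-11.9 percentage points, kidney minus spleen) and regulatory T-like cells (-6.31 points) lower in kidney in 5 of 5 mice. In the same clusters the cytotoxic-like difference was -2.81 points, with 3 of 5 mice higher in kidney, in place of -24.2 points. Cycling-like cells (1.35% against 2.21%, exact p = 0.312) and follicular helper-like cells (4.31% against 8.16%, exact p = 0.5) went both ways among the mice. The follicular helper-like mean difference went from -3.85 to -1.10 points without WT1, and the cycling-like one from -0.859 to -0.315 points without WT2. The sort gate was CD3, TCR beta, CD4 and CD8a staining in both organs, per the labels.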

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

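The tests of UMIs per cell between mice, of the splits of the 5 mice and of the splits that part all pairs were chosen after the result was seen.

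A gap test within groups of 5 mice picked out 5 values in 52 groups, where chance alone picks out about 1 in 20. Cycling-like cells made up 2.93% of kidney cells in WT2 (95% Wilson interval 2.18 to 3.92) and between 0.739% and 1.12% in the other mice. In spleen they made up 5.97% in WT2 (4.61 to 7.68) and between 0.831% and 2.10% in the others. Osgin1, an oxidative stress-induced growth inhibitor, stood at 56.5 CPM in kidney of WT2 and between 10.7 and 19.6 CPM in the others. Phactr1, which encodes an actin-binding phosphatase regulator, stood at 307 CPM in spleen of WT1 and between 8.55 and 29.7 CPM in the others. Egr2, a transcription factor induced by T cell receptor signals, stood at 45.4 CPM in spleen of WT1 and between 19.2 and 24.0 CPM in the others.

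For 3 lists the genotype effect differed between the organs by the interaction test with camera: the median log2 difference, kidney minus spleen, was 0.80 for cell cycle genes, 0.63 for cytotoxic effectors and -0.45 for type I interferon genes. Each of the 3 calls was lost with an estimated correlation (adjusted p = 0.356). In the 2399 cells of the second day, which fall under 4 mice and both organs and entered no comparison, Kap, a transcript of the kidney proximal tubule, stood at 35.8 CPM (95% Poisson interval 32.1 to 39.8), and over all cells kept of each mouse and organ of the first day it stood between 0 and 2.02 CPM. Gpx3, another transcript of the tubule, did not follow it, with 85.7 CPM (79.9 to 91.7) in them and 1.04 to 846 CPM on the first day.

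The spleen genotype comparison called 33 genes by edgeR, while the split of WT2 and WT3 from the other 3 mice called 861 in spleen and 1296 in kidney, where the genotype called 0 by edgeR (1124 at an unadjusted p under 0.05) and 90 by DESeq2. A split that calls several times the real count points to a structure of the samples, here 2 WT mice apart from WT1 and both KO mice. The 10 splits of 2 against 3 mice are too few for a share under 0.05, and in spleen 2 of 10 gave as many genes as the real one (33, highest other 861). In kidney the split of KO1 and WT1 from the others called 0 genes by edgeR. It gave 1128 at an unadjusted p under 0.05, against 1124 for the genotype. The tables argue against UMIs per cell as the source, since the median UMIs per cell of WT2 and WT3 stood at 0.948 times that of the other mice in spleen and 0.962 times in kidney. Median mitochondrial percent did follow the split, with 0.854 and 0.832 in kidney of WT2 and WT3 against 1.16 to 1.29 in the others and 1.05 and 1.09 against 1.40 to 1.44 in spleen. The mouse numbers of the key follow it too. WT2 and WT3 are mice 3473 and 3474, while KO1, KO2 and WT1 are mice 3409, 3413 and 3415. What the numbers stand for is not given in the sources used here, and WT1 is the only WT mouse numbered close to the KO mice. Cell quality stays open, as does any difference that the labels do not give, such as the start of tamoxifen.

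Between kidney and spleen 2635 genes were called, and of 100 splits drawn from the 126 possible ones, 1 gave as many, the real one, with 156 as the highest other. Most of the other splits drawn left both organs of some mice on the same side, and the organs of a WT mouse followed each other (r from 0.539 to 0.775). The drawn splits as a set are therefore no fair measure of chance. The 16 splits that part all 5 pairs are too few for a share under 0.05, with 2635 genes for the real split, 0 for the highest other and 1 split as large.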

How the results depend on the processing

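The settings without both WT2 and WT3, without cluster 8, HTODemux singlets, edgeR with a term for each mouse, the re-made clusters and the mice left out for shares and Ezh2 were tests chosen after the result was seen. Kidney genotype genes numbered 0 by edgeR (1124 at an unadjusted p under 0.05) and 90 by DESeq2, 545 with no filter, 172 without both WT2 and WT3, and 0 to 1249 with 1 mouse left out, the highest without WT1. Spleen genotype genes, 33, became 660 by DESeq2, 449 with no filter and 1573 without both WT2 and WT3, each with all 33 kept, 115 with HTODemux singlets (30 kept), and 0 to 2294 with 1 mouse left out, the highest again without WT1. Interaction genes, 0 by edgeR (362 at an unadjusted p under 0.05), became 1 by DESeq2, 18 without both WT2 and WT3, and 0 to 3 with 1 mouse left out. With the mouse as a block they were 2 in edgeR and 0 in limma-voom. Genes between kidney and spleen, 2635, became 4082 with the replicate block (2623 kept) and 1385 to 2935 with 1 mouse left out, where fewer samples were tested. Apart from these and the lists between organs, the paired fit changed no count by over 1.5 times. Lists called in kidney, 7, became 14 without both WT2 and WT3 and 0 with an estimated correlation. Lists in spleen, 5, became 12 with no filter, 13 without both, 0 with an estimated correlation and 6 to 11 with 1 mouse left out. Interaction lists, 3, became 6 with no filter, 9 with all cells kept, 5 without both, 0 with an estimated correlation and 3 to 10 with 1 mouse left out. Lists between organs, 1, became 4 with no filter, 4 with the block, 10 without both and 1 to 2 with 1 mouse left out. With an estimated correlation that list stayed called (1), but 0 lists were called with the block, without KO1, KO2 or WT1, or without both. Klrg1 in spleen reversed, from a log2 fold change of -1.59 to 1.53 without both. The share of cycling-like kidney cells, KO minus WT, was -0.557 percentage points and ran from -0.973 to 0.123 with 1 mouse left out, reversed without WT2. That of follicular helper-like spleen cells was 0.395, became -0.102 with the fixed genes kept in the clustering and ran from -3.61 to 8.02 with 1 mouse left out. All other shares and Ezh2 kept their sign under each setting run, though not always their size: regulatory T-like cells in spleen went from 11.5 points to 6.59 without KO2 and 5.19 at resolution 1.5, and in kidney from 2.63 to 1.23 at resolution 1.5 and 7.05 without the genes called between genotypes. Follicular helper-like cells in kidney went from 2.83 to 0.475 without KO1, 5.19 without KO2 and 5.45 without WT1, and cycling-like cells in spleen from -2.14 to -0.693 without WT2. Cytotoxic-like cells in kidney went from -3.20 to -2.08 without WT3, -4.83 without WT1 and -20.4 without the genes called between genotypes or organs. In spleen they went from -39.9 to -26.3 without those genes, -31.3 at resolution 1.5 and -31.1 with the fixed genes kept in the clustering. With the fixed genes kept, 740 cells led by Ccl3, Havcr2, Ccl4 and Lag3, among others, took the name inhibitory-receptor-high-like. Between organs, naive-like cells went from -12.2 to -5.32 points without KO1 and cytotoxic-like cells from -24.2 to -14.9 without WT2, follicular helper-like cells from -3.85 to -1.10 without WT1 and cycling-like cells from -0.859 to -0.315 without WT2. Naive-like cells stood 34.8 to 50.1 points higher in KO spleen and 11.7 to 18.3 in KO kidney with 1 mouse left out, and Ezh2 at -1.13 to -0.72 on the log2 scale in kidney and -1.60 to -0.96 in spleen. Of the other single-gene values, 4503 stayed on their side of the threshold, 404 came past it and 148 lost it. Without a KO mouse, or without both WT2 and WT3, an arm holds 1 sample, assumed to vary like the others. Beyond the fewer samples or more genes that a setting brings by construction, the cause was not tested. Minimums of 10 and 100 cells removed nothing and say nothing of stability. The kidney HTODemux singlets were too few for a value, shares at 5% mitochondrial UMIs or 500 genes were not re-clustered, and the alternatives for organs as 1 sample each were not run because mice could be told apart. Depth limits kidney KO2 most, with 824732 UMIs in 205 cells.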

Other observations

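The test of naive-like cells within a range of UMIs was chosen after the result was seen, as were the clusters and Trbv genes described here. Most kidney CD4+ T cells fell into clusters that the fixed markers did not name. Cluster 1, led by Esm1 (endocan), Ppp2r2c, the Notch target Nrarp and the adaptor Grb7, made up 2.65% of kidney cells in KO1 (95% Wilson interval 1.70 to 4.10), 5.94% in KO2 (3.50 to 9.89), 9.27% in WT1 (7.96 to 10.8), 78.3% in WT2 (76.1 to 80.4) and 73.0% in WT3 (70.1 to 75.7). Cluster 3, led by Ramp3, Fosl2, Crem and Tnfsf11 (RANKL), made up 50.8% in KO1 (47.1 to 54.4), 35.6% in KO2 (29.6 to 42.2), 43.6% in WT1 (41.2 to 46.0), 1.02% in WT2 (0.621 to 1.68) and 7.39% in WT3 (5.89 to 9.24). Cluster 8, led by granzyme A and the NK receptor genes Klrc1, Klrk1 and Klrd1, with Cd8a and Cd8b1 raised, made up 8.37%, 15.5%, 13.6%, 7.57% and 4.22% in KO1, KO2, WT1, WT2 and WT3.

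T cell receptor beta variable genes, read from the gene counts, were spread over many segments. The leading Trbv gene of a mouse and organ was carried by 11.6% (Trbv13-2, spleen of KO1) to 17.0% (Trbv26, kidney of WT3) of the cells with a Trbv call. Of the classes with at least 30 such cells, the spleen cytotoxic-like cells of KO2 stood apart, with Trbv13-1 in 52.5% of 59 cells (95% Wilson interval 40.0 to 64.7). Cytotoxic-like cells made up most spleen cells of WT2 and WT3, and 1 dominant clone per mouse was tested as a hypothesis. The leading Trbv gene was carried by 22.8% of them in WT3 (Trbv20, 20.3 to 25.6) and 14.1% in WT2 (Trbv19, 11.4 to 17.3), which argues against a single clone as the main source in either spleen, and smaller clones were not tested.

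Spleen naive-like cells were more frequent in KO than in WT mice. Among cells of 2500 to 4500 UMIs the lowest KO share was 19.7 times the highest WT share, which argues against UMIs per cell as the cause. Among HTODemux singlets the ratio was 17.9, which argues against cells with mixed tags as the cause. A swapped block or a wrong join of tags to the key would give the same ratio, so those stay open. Thinning each cell to 2000 UMIs and counting cells with at least 4 naive-marker UMIs gave a ratio of 1.53 (1.24 before thinning). That lay on the side set beforehand for UMIs per cell as the cause. The measure did not show the pattern in unthinned cells, though, and so decides nothing. There 88.1% and 78.0% of spleen cells in KO1 and KO2 and 62.7%, 40.6% and 52.3% in WT1, WT2 and WT3 passed the count. Many WT cells outside the naive-like clusters thus also carried naive-marker UMIs. The genotype may account for the difference in naive-like cells, as the design names it, and this stays untested against other differences between the 5 mice, such as the start of tamoxifen.

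Ezh2 was lower in KO mice in both organs, and dividing cells carry more of it, so a difference in cell makeup could lower it without a deletion. Without cycling-like cells 100.2% of the kidney log2 difference was kept (97.7 to 106 with 1 mouse left out) and 92.6% of the spleen difference (90.2 to 98.6), which argues against cycling cells as the main source. Without naive-like and cycling-like cells 58.4% of the spleen difference was kept (51.0 to 66.6), so the naive-like share may account for a part. In the cells left, WT1 (71.2 CPM by library total) lay near KO1 (67.2) and KO2 (61.6), and what was kept came from WT2 (133) and WT3 (130), the 2 mice that also stood apart in their other genes. Deletion of Ezh2 in the KO cells stays open, since the labels do not give the floxed exons and KO cells still held 52.6 CPM in spleen.

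The 2399 cells of the second day, which were given to no mouse, held 9608748 UMIs. Ezh2 stood at 94.6 CPM in them (95% Poisson interval 88.6 to 101), Cd4 at 228 (218 to 238), Foxp3 at 48.3 (44.0 to 52.9) and Ccl5 at 2293 (2263 to 2324). Over all cells kept of each mouse and organ of the first day, Ezh2 ran from 52.3 to 179 CPM by library total and Foxp3 from 0.822 to 130 CPM.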
